A study of Mus musculus with 4 samples.

How the data were processed

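The samples were macrophages from the peritoneal cavity of C57BL/6 mice aged 8 to 12 weeks, drawn into the cavity by a 1 mL injection of 4% thioglycolate 3 days earlier, per the labels' protocols. The cells that adhered to the plate were kept for 6 h with fatty acid complexed to bovine serum albumin (BSA), or with vehicle. The control is labelled as BSA alone, while the treatment protocol names ethanol and KOH as the vehicle. Each fatty acid was given at 500 µM. RNA of 3 samples was pooled in each group, after an RNA integrity number above 8.0, and 100 ng of total RNA was labelled for 1 Affymetrix array per group. The series used here therefore holds 4 arrays and 1 measurement per group. It is not said whether the 3 samples of a pool came from separate mice.

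The values deposited by the authors are on a log2 scale and were made with RMA, a method that corrects background, normalises arrays together by quantiles and summarises probes, per the submitters' processing notes. The version, the level of summary and the genome build are not given in the sources used here. The log2 scale was read from the range of the values, and no coordinates are printed. The table holds 35556 probes. The platform annotation lists 23410 of them, with exactly 1 gene for 21789 and several genes for 1621. The other 12146 probes have no listed gene here. Symbols were checked by Entrez ID against a RefSeq gene table of assembly GRCm38.p6, used for names alone. It held the ID of 21698 of the probes with 1 gene, and 0 symbols needed an update. No column belonged to an unknown sample.

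Probes with exactly 1 gene gave 19938 genes. The probes of the 999 genes with more than 1 probe were averaged. A gene was kept when the highest of its 4 values was at or above the median of all values, log2 7.09, which left 11174 genes. This filter is a measure of brightness and not a detection call. Probes of gene families and pseudogenes can bind transcripts of related genes, so that values of such genes, ribosomal protein pseudogenes among them, are uncertain.

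With 1 array per group there is no estimate of the spread between samples, so no test, interval or p-value was computed for a difference between groups. The shuffles and bootstrap intervals behind the closing paragraphs run over genes and describe the spread among genes, not among samples. The number of arrays limits the precision of every value. For each of 6 comparisons, 3 with the control and 3 between fatty acids, the difference in log2 value was taken per gene, and genes at least 1.5-fold higher or lower were counted. Gene lists were described by the median difference of their kept members and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart below percentile 0.5 or above 99.5, which 1% of random lists do. Lists with fewer than 5 kept members have values and no percentile. These percentiles describe the arrays and are not tests of the treatments.

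The comparisons, the lists, the genes to name and the alternatives were chosen before the data were examined. The 35 lists were written from general knowledge and hold 708 genes, of which 60 without a probe of exactly 1 gene are not analysed here. Named were the 10 genes with the largest difference each way in each comparison with the control, the 6 each way in each comparison of fatty acids, 32 genes set in advance, up to 4 members of each described list, and the 5 genes each way with the largest smallest difference across the 3 comparisons with the control. Predicted gene models, small RNA genes with systematic names and receptor cluster names were left out of the ranking. Of the 32 genes set in advance, 29 were measured and 3 are not analysed here.

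Comparisons with the control share 1 array. Their overlaps and correlations are given beside 100 simulations of unchanged arrays that share a control. The noise in these simulations came from the control and linoleic acid arrays, the pair with the smallest spread, and holds any real difference between them. Correlations of differences that share no array were added. The counting was tested on simulated data labelled as palmitic acid against the control, with 11174 genes and 200 changed genes at each size. Its noise was drawn as normal from the spread of the control and linoleic acid arrays. That pair had a robust SD of 0.110, beside 0.194 for palmitic acid and the control. The results of this test hold for that smaller noise and not for the palmitic acid comparison as measured. The counting called 44.5% of genes with a true 1.5-fold difference, 100.0% at 2-fold and 100.0% at 3-fold, and 0 unchanged genes. Of 200 simulated lists of 20 genes, 1.0% stood apart with no shift, 78.5% with a shift of 0.1 and 100.0% with a shift of 0.2 in log2.

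Alternatives were centring each array on its median, repeating the quantile normalisation, no filter, a stricter filter at the 75th percentile, a filter on the mean, the brightest probe of each gene, and values below the floor set to it. For lists, random lists without matching and lists without members of other lists were tried, and for overlaps a 2-fold size. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.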

Results

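Gene expression was measured in mouse peritoneal macrophages kept for 6 h with vehicle or with 500 µM of palmitic acid (16 carbons, 0 double bonds), oleic acid (18 carbons, 1 double bond) or linoleic acid (18 carbons, 2 double bonds). Each group is 1 array of RNA pooled from 3 samples. There are no replicates, so that no test or interval of a difference between groups is possible, and every difference below is one between 2 arrays. The median log2 value over all probes was 7.09 in the control, 7.08 with palmitic acid, 7.07 with oleic acid and 7.13 with linoleic acid. Over all probes the array pairs correlated between r = 0.991 (palmitic and oleic acid) and r = 0.996 (control and oleic acid).

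The first comparison asked how macrophages exposed to the saturated palmitic acid differed from the control. Hilpda, which codes for a lipid droplet protein, had the largest difference, from log2 9.32 in the control to 11.49 in the palmitic acid array. The lipid droplet coat gene Plin2 was higher by 1.20 and Cpt1a, which codes for the enzyme that commits fatty acids to mitochondrial import, by 0.93. Genes of the integrated stress response were higher, among them Sesn2 by 1.33, Chac1 by 1.26, Ppp1r15a by 1.11 and Ddit3, which codes for the transcription factor CHOP, by 0.91. Genes of cholesterol synthesis were lower, with Idi1 at a log2 difference of -1.04 and Hsd17b7 at -0.90. The growth factor gene Csf2 had the largest difference downward, -1.52.

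Among 11174 kept genes, 242 were at least 1.5-fold higher and 157 at least 1.5-fold lower in the palmitic acid array, and 44 and 33 were so by 2-fold. Higher genes were 60.7% of those beyond 1.5-fold, and 51.7% after a repeated quantile normalisation. Besides Hilpda and Sesn2, the highest were Rsbn1 (1.61), Csrnp1 (1.59), Jun (1.53), Plagl1 (1.48), Dusp10 (1.39), Rgcc (1.38), Lrrc32 (1.36) and Hamp (1.32). Hamp codes for hepcidin, a regulator of iron export. Besides Csf2, the lowest were Gpr85 (-1.49), Gpr18 (-1.44), Shisa3 (-1.33), Icosl (-1.32), Bcor (-1.31), Pdgfrb (-1.29), Cxcl9 (-1.29), Cp (-1.28) and Scd2 (-1.28). Scd2 codes for a fatty acid desaturase and Icosl for a ligand of the T cell costimulator ICOS.

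Of the 28 kept genes of the ATF4 and stress response list, 5 were at least 1.5-fold higher with palmitic acid and 0 lower, with a list median of 0.20 at percentile 99.98 of random lists. The genes named above and Trib3 (0.76) made up the 5, while Atf4 itself was higher by 0.43, Atf3 by 0.49 and Asns by 0.17. Of 26 endoplasmic reticulum chaperone and XBP1/ATF6 target genes, 4 were at least 1.5-fold higher, namely Dnajb9 (1.02), Sec24d (0.87), Syvn1 (0.65) and Pdia4 (0.59). The list median was 0.19 at percentile 99.93, with Hspa5 at 0.34 and Xbp1 at 0.10. Of 20 NRF2 antioxidant genes, 3 were at least 1.5-fold higher, Srxn1 (0.74), Gclm (0.72) and the heme oxygenase gene Hmox1 (0.63), with a median of 0.20 at percentile 100.0. Of 26 autophagy genes, 5 were at least 1.5-fold higher, among them Fnip2 (0.96), Ulk1 (0.70), Atg14 (0.68) and Flcn (0.65). The autophagy median of 0.19 stood apart at percentile 99.92, but no longer did so once members of other lists were left out.

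Of 20 cholesterol synthesis and uptake genes, targets of the sterol-regulated transcription factor SREBP2, 10 were at least 1.5-fold lower with palmitic acid and 0 higher, with a list median of -0.59. Lss had a difference of -0.89 and Hmgcs1 of -0.87. Of 16 fatty acid synthesis and desaturation genes, 3 were at least 1.5-fold lower, Scd2, Elovl6 (-1.01) and Fads2 (-0.98), while Fasn lay at -0.55 and Scd1 at -0.31. The median of this list was -0.25. The 13 LXR target genes had a median of -0.18 at percentile 0.065, with Mylip at -0.98, Rnf145 at -0.77, Abca1 at -0.31 and Abcg1 at -0.18. Of 16 PPAR target genes, 3 were at least 1.5-fold higher, Hilpda, Plin2 and Cpt1a, with a median of 0.21 at percentile 99.93, and Angptl4 was higher by 0.39 and Fabp4 by 0.33. The lipid droplet and triglyceride list (0.11 at percentile 98.6) and the fatty acid oxidation enzymes (-0.03, with 12 of 22 below 0) did not stand apart with palmitic acid.

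Cytokine genes did not stand apart as a list with palmitic acid, with a median of -0.06 over 30 genes. Of these, 3 were at least 1.5-fold lower, Csf2, Lif (-0.70) and Il6 (-0.59), and 0 were higher. Il1b (-0.13), Tnf (0.09), Ptgs2 (-0.07), Cxcl2 (0.08) and Ccl2 (-0.0037) lay close to the control. In the control array Il1b was at log2 13.78, Tnf at 13.76, Ptgs2 at 13.81 and Cxcl2 at 13.73, close to the highest value of any probe, 14.4. Of the 30 genes, 12 lay at or above 13 in the control array and 10 below 12. The 25 interferon-stimulated genes, with Cxcl10 at 13.83 and Rsad2 at 13.74 in the control, had a median of 0.04 and did not stand apart. Many of these genes were thus already bright without fatty acid, and their differences are not from a low baseline. Among alternative activation genes, the chemokine genes Ccl22 (-1.16) and Ccl17 (-0.69) were at least 1.5-fold lower, and the list median of -0.08 did not stand apart. The fatty acid receptor gene Gpr84 lay at -0.70, and the fatty acid transporter gene Cd36 at -0.01. Cd36 was at log2 13.24 in the control, a brightness at which palmitic acid differences were small in general (robust SD 0.082). Its value therefore does not show that Cd36 was unchanged. Beside these lower groups, all 9 kept markers of mesothelial cells and fibroblasts were lower in the palmitic acid array, with a median of -0.25 at percentile 0.14 and Pdgfra at -0.86. The 17 macrophage markers had a median of -0.05.

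**Figure D1:**
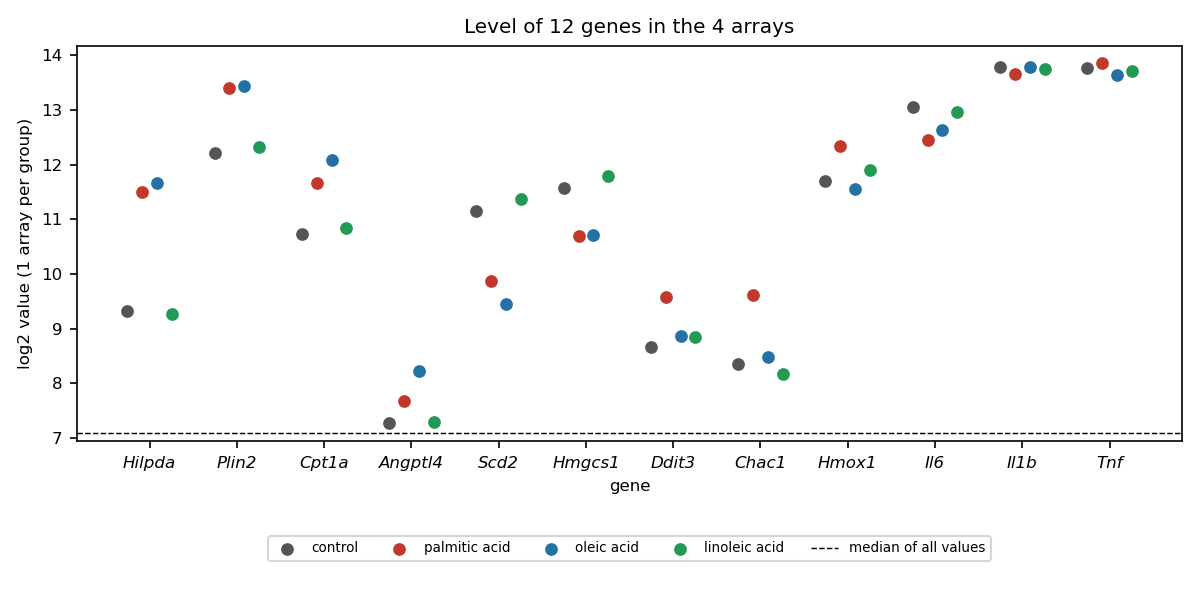
Log2 value (vertical axis) of 12 genes (horizontal axis) in the control, palmitic, oleic and linoleic acid arrays, 1 point per array, with the median of all values as a dashed line. Hilpda lies at 9.32 and 9.27 in the control and linoleic acid arrays and at 11.49 and 11.66 in the palmitic and oleic acid arrays, while Il1b and Tnf lie near the top of the scale in all 4.

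The comparison of oleic acid with the control asked the same of a monounsaturated fatty acid. Hilpda again had the largest difference, 2.34, followed by Cpt1a (1.35), Hamp (1.28), the polyamine oxidase gene Smox (1.25) and Plin2 (1.22). Cholesterol synthesis genes were lower in the oleic acid array, with Lss at -1.13, Cyp51 at -1.12, Idi1 at -1.08 and Hsd17b7 at -1.05. Scd2 had the largest difference downward, -1.69. Stress response genes lay close to the control, with Ddit3 at 0.21, Chac1 at 0.13 and Trib3 at 0.13.

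In the oleic acid array 42 genes were at least 1.5-fold higher and 38 at least 1.5-fold lower than in the control, and 6 and 8 were so by 2-fold. Arrdc3 (1.07), Cd300a (0.95), the chemokine receptor gene Ccr1 (0.95), Angptl4 (0.95) and Dusp1 (0.87) completed the 10 highest. Shisa3 (-1.21), the potassium channel gene Kcnj2 (-1.09), Sqle (-1.02), Mvd (-1.0) and Fasn (-0.95) completed the 10 lowest. Kcnj2 was dim, and with values below the floor set to it its difference was -0.29.

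Of the 20 cholesterol synthesis and uptake genes, 13 were at least 1.5-fold lower with oleic acid and 0 higher, with a median of -0.83. Of the 16 fatty acid synthesis and desaturation genes 4 were at least 1.5-fold lower, Scd2, Fasn, Fads2 (-0.92) and Elovl6 (-0.76), with a median of -0.29. Of the 16 PPAR target genes 5 were at least 1.5-fold higher, with a median of 0.29 at percentile 100.0. Fatty acid oxidation enzymes had a median of 0.11 at percentile 99.77, with Cpt1a, Acaa2 (0.60), Slc25a20 (0.57) and Etfdh (0.41) the highest of 22, and did not stand apart once members of other lists were left out. NRF2 antioxidant genes were lower, with a median of -0.12 over 20 genes, 0 of them beyond 1.5-fold, and Gclm at -0.53. That call too was lost without members of other lists. The stress response list (0.03) and the chaperone list (0.04) did not stand apart. Among cytokine genes, with a median of -0.05, Il23a was higher by 0.62, Il6 lay at -0.42 and Il1b at 0.0043. The 9 mesothelial and fibroblast markers had a median of -0.01, and the 17 macrophage markers of 0.05.

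**Figure D2:**
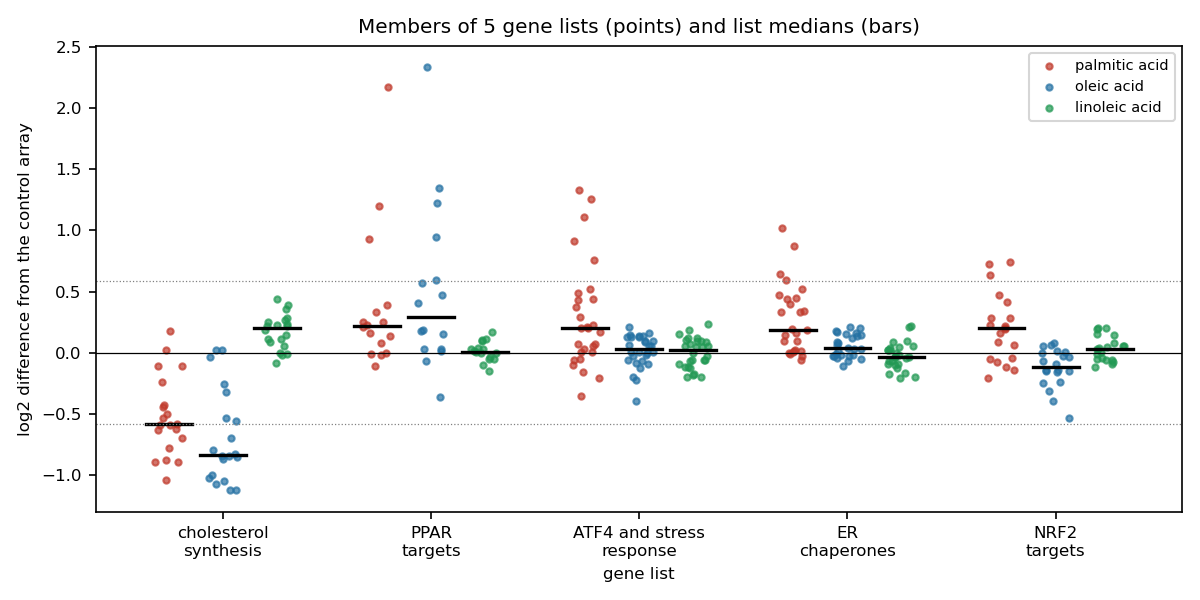
Log2 difference from the control array (vertical axis) of the kept members of 5 gene lists (horizontal axis) in the palmitic, oleic and linoleic acid arrays. Points are genes, black bars are list medians and dotted lines mark 1.5-fold; the cholesterol synthesis medians lie at -0.59, -0.83 and 0.20, and the stress response medians at 0.20, 0.03 and 0.02.

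The comparison of linoleic acid with the control addressed a polyunsaturated fatty acid. Counted in kept genes, the linoleic acid array lay close to the control: 4 genes were at least 1.5-fold higher, 4 at least 1.5-fold lower and 0 beyond 2-fold. Over all probes it was no closer than oleic acid, with r = 0.995 with the control beside 0.996 for oleic acid. Hilpda (-0.05), Plin2 (0.11), Cpt1a (0.11), Angptl4 (0.01) and Ddit3 (0.18) were near their control values. Cholesterol synthesis genes were slightly higher, with Hsd17b7 at 0.44, Stard4 at 0.39, Lss at 0.35 and Srebf2 at 0.29. The list median of 0.20 over 20 genes, 16 of them above 0, stood at percentile 100.0, with 0 genes beyond 1.5-fold.

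The highest genes with linoleic acid were Eid3 (0.76), Tmem86b (0.69), Spaca6 (0.60), Pou5f2 (0.60), Adam4 (0.56) and Slc13a3 (0.53), followed by Dnajb6, Glrx3 and Klhl34 at 0.49 and Stx16 at 0.48. The lowest were Bex1 (-0.72), Car6 (-0.60), Rps19-ps3 (-0.56), Rprl1 (-0.53), Mrps36 (-0.53), Rny1 (-0.51), H4c6 (-0.50), Zfp971 (-0.48), Zfp874b (-0.45) and Gnpda2 (-0.44). With values below the floor set to it, Adam4 lay at 0.02 and Car6 at -0.18. LXR target genes had a median of 0.12 and stood apart in 3 of 7 alternatives. The PPAR list (0.0094), the stress response list (0.02) and the cytokine list (0.01) did not stand apart, and chaperone genes lay slightly lower, at -0.03, a call lost after a repeated quantile normalisation. The 9 mesothelial and fibroblast markers had a median of 0.03 and the 17 macrophage markers of -0.0023. With each array centred on its median the counts beyond 1.5-fold were 2 higher and 7 lower, and after a repeated quantile normalisation 2 and 9. The filters tipped them the other way. Higher genes were 69.0% of those beyond 1.5-fold without the filter and 75% with the stricter filter.

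The fatty acids were compared directly at the same concentration and time. Palmitic and oleic acid arrays both held high Hilpda, Plin2 and Hamp, with differences between them of -0.16, -0.03 and 0.03. They differed in stress response genes, all given as palmitic minus oleic acid: Chac1 by 1.13, Ddit3 by 0.70 and Trib3 by 0.63. The NRF2 antioxidant gene Hmox1 was higher with palmitic acid by 0.79. Arrdc3 was the gene with the largest difference, -2.31, higher than the control with oleic acid and lower with palmitic acid. No interval of any of these differences can be had.

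Between the palmitic and oleic acid arrays 203 genes were at least 1.5-fold higher and 185 at least 1.5-fold lower with palmitic acid. The higher genes were 52.3% of these, and 42.5% after a repeated quantile normalisation, so that the scaling decides which side is larger. The highest were Intu (1.49), Htr2a (1.46), the matrix protein gene Ccn2 (1.42), Lrrc32 (1.36), Plagl1 (1.32) and Jun (1.32). Below Arrdc3 came Gpr18 (-1.53), the cyclin gene Ccnd2 (-1.53), Tagap (-1.39), Icosl (-1.35) and the transporter gene Slc16a6 (-1.34). The stress response list had a median difference of 0.20, with 5 of 28 genes at least 1.5-fold higher, and the NRF2 list of 0.27, with 5 of 20. Fatty acid oxidation enzymes had a median of -0.21, with 0 of 22 beyond 1.5-fold. The cholesterol synthesis list (0.16) and the PPAR list (-0.10) did not stand apart between these 2 arrays. In the cholesterol list 15 of 20 genes were higher with palmitic acid, 1 of them by 1.5-fold. This was Insig1, with a direct difference of 0.97. Against the control it lay at 0.17 with palmitic and at -0.80 with oleic acid. The 9 mesothelial and fibroblast markers had a median of -0.19.

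Palmitic acid differed from linoleic acid at Hilpda (2.22), Jun (1.5), Csrnp1 (1.46), Chac1 (1.46), Rsbn1 (1.44) and Fbxo32 (1.41), all higher with palmitic acid. Lower with palmitic acid were Cxcl9 (-1.67), Cp (-1.62), Hdc (-1.57), Gpr85 (-1.52), Scd2 (-1.51) and Gpr18 (-1.49). Hdc codes for the enzyme that makes histamine. In all, 177 genes were at least 1.5-fold higher and 225 at least 1.5-fold lower. Higher genes made up 44.0% of these, but 53.1% with each array centred on its median. Cholesterol synthesis genes had a median of -0.75, with 14 of 20 at least 1.5-fold lower, PPAR targets of 0.20 with 3 of 16 higher, stress response genes of 0.22 with 6 of 28 higher, and chaperone genes of 0.28 with 3 of 26 higher. The 9 mesothelial and fibroblast markers had a median of -0.24.

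Linoleic and oleic acid, which have the same chain length and differ by 1 double bond, were compared next. Scd2 (1.92), Hsd17b7 (1.48), Lss (1.48), Shisa3 (1.35), Fasn (1.30) and Mvd (1.26) were higher with linoleic acid. Hilpda (-2.39), Arrdc3 (-1.33), Cpt1a (-1.24), Hamp (-1.16), Plin2 (-1.11) and Cd300a (-1.10) were lower. Of 20 cholesterol synthesis genes 15 were at least 1.5-fold higher with linoleic acid, with a median of 0.98, and of 16 PPAR target genes 4 were at least 1.5-fold lower, with a median of -0.35. Stress response genes (-0.02) did not stand apart. In all, 79 genes were at least 1.5-fold higher and 38 lower, so that 67.5% of these genes were higher with linoleic acid. That share was 52.2% with each array centred on its median and 50.4% after a repeated quantile normalisation.

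Palmitic and oleic acid shared genes beyond 1.5-fold against the control. The 14 shared higher genes included Hilpda, Cpt1a, Plin2, Hamp, Smox, Cd300a, Dusp1 and Dusp10. The 22 shared lower genes included Scd2, Shisa3, Idi1, Lss, Cyp51, Sqle, Mvd, Hmgcs1, Elovl6, Fads2 and Pdgfrb. Independent lists of these sizes would share 0.91 and 0.534 genes, and simulated unchanged arrays with a common control shared 0 and 0. The simulated noise put on average 0.00667 genes per comparison beyond 1.5-fold, so that these zeros say nothing of what the shared control adds. That part of the counts is not known, since the control array cannot be split. Palmitic minus linoleic acid and oleic acid minus control share no array. Their medians were -0.75 and -0.83 for the cholesterol synthesis list and 0.20 and 0.29 for the PPAR list. Noise of the control array cannot enter both, so that the common direction of these 2 lists does not need it. Palmitic and linoleic acid shared 1 higher gene, Eid3, and 0 lower genes, and oleic and linoleic acid shared 0 either way. Lower with palmitic and higher with oleic acid by 1.5-fold were 4 genes, Arrdc3, Slc16a6, the Fc receptor gene Fcgr1 (-0.66 and 0.65) and Cyp1b1, the last named after its values were seen.

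**Figure D3:**
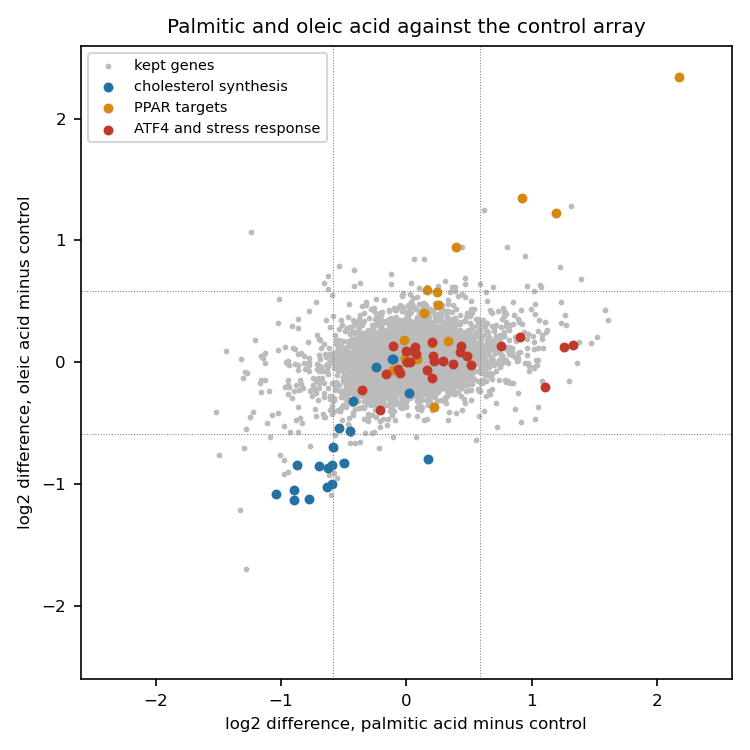
Log2 difference from the control array with palmitic acid (horizontal axis) and oleic acid (vertical axis) for the kept genes, 1 point per gene, with dotted lines at 1.5-fold. Cholesterol synthesis genes lie toward the lower left (medians -0.59 and -0.83), PPAR targets toward the upper right (0.21 and 0.29), and stress response genes spread along the palmitic acid axis (0.20 and 0.03).

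Across genes, which are not independent replicates, differences from the control correlated at r = 0.258 for palmitic and oleic acid, 0.274 for palmitic and linoleic acid and 0.140 for oleic and linoleic acid. Simulated unchanged arrays with a common control gave 0.498, 0.50 and 0.50. The covariances were 0.00998, 0.00843 and 0.00261, beside simulated values of 0.00616, 0.00617 and 0.00617. All 3 differences subtract the same control array, so that a single low or high control value gives a difference of the same sign in all 3, and the following genes are the extremes of that ranking. Higher in all 3 fatty acid arrays were Il10, with the smallest difference 0.37, Lrp4 (0.32), Thap2 (0.31), Mtfmt (0.30) and Tbc1d25 (0.30). Lower in all 3 were Rps19-ps3, whose difference nearest to 0 was -0.39, Syndig1l (-0.30), Spata48 (-0.27), Ttc32 (-0.27) and Acot10 (-0.26). Il10 lay at log2 6.99 in the control, below the floor, and Thap2 and Spata48 were near it too.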

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

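The tests of the same RNA on both arrays, of exchanged labels, of measurement noise, of fewer fibroblasts and of a ceiling were chosen only after the result was seen.

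Several lists stood apart in opposite directions from the control in different fatty acids, with 1 array each, and none of these differences was tested. Cholesterol synthesis genes were lower with palmitic and oleic acid and higher with linoleic acid, with a median of -0.75 for palmitic minus linoleic acid and 0.98 for linoleic minus oleic acid. LXR target genes were lower with palmitic acid and higher with linoleic acid, with a direct median of -0.38, but the linoleic acid call held in only 3 of 7 alternatives. Chaperone genes were higher with palmitic acid and lower with linoleic acid, with a direct median of 0.28, but the linoleic acid call was lost after a repeated quantile normalisation. NRF2 antioxidant genes were higher with palmitic acid and lower with oleic acid, with a direct median of 0.27, but the oleic acid call was lost without members of other lists.

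Probes with no listed gene, which enter the medians and correlations over all probes but no gene or list value above, also differed from the control. At least 2-fold higher were 291 of these 12146 probes with palmitic acid, 43 with oleic acid and 116 with linoleic acid, and 53, 128 and 82 were at least 2-fold lower. What these probes measure is not analysed here.

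The linoleic acid array lay close to the control by the count of kept genes, with 8 of 11174 beyond 1.5-fold. By other measures it was about as close as oleic acid. The robust SD of differences from the control was 0.110 with linoleic and 0.116 with oleic acid. Over all probes the correlations with the control were 0.995 and 0.996. The same RNA pool on both arrays is argued against by the cholesterol synthesis list, whose median of 0.2038 lay outside the range of random lists from -0.03 to 0.12. It is not excluded, since random lists do not cover array-wide effects that move lists together. Ribosomal protein genes (-0.08) and oxidative phosphorylation genes (-0.03) also stood apart between these 2 arrays. Exchanged labels of these 2 arrays stay open. An exchange would change every comparison with the control. It would make the cholesterol list lower with linoleic acid, and likewise the LXR list lower and the chaperone list higher, as with palmitic acid. The opposite directions given above for linoleic acid would then be lost. The cholesterol list's differences of palmitic and oleic acid from the control would then be those from the array labelled linoleic acid. Their medians were -0.75 for palmitic minus linoleic acid and 0.98 for linoleic minus oleic acid, so that the list would stay lower with palmitic and oleic acid. The PPAR target list, higher with those 2, had a median of 0.0094 inside its range of random lists and shows no direction. That linoleic acid changed little in these cells, or did not reach them, stays open and untested, since there is no second untreated pool.

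The palmitic acid array lay farthest from the others, with 399 genes beyond 1.5-fold of the control. Random noise of that array as the whole cause is argued against by 11 of 29 lists that stood apart, where 1000 shuffles of the differences among genes of like brightness gave at most 5. A trend with brightness is argued against by the 387 genes that stayed beyond 1.5-fold once a lowess trend was removed, 216 higher and 171 lower. Fewer fibroblasts or mesothelial cells, which the washing of the plated cells could also affect, would as the whole cause lower their markers as much as the 157 lower genes (median -0.78). Against that, the marker median was -0.2466, with quartiles of -0.28 and -0.19, and the abundant Dcn, at log2 10.8 in the control, lay at -0.21. The 157 genes were picked in these arrays for a difference of at least 1.5-fold, so that their median had to lie beyond it. The comparison with them therefore leans against the explanation and does not exclude it. A partial loss of these cells stays open, since all 9 markers were lower and the list stood apart, with Pdgfra at -0.86. Pdgfrb, outside the list, lay at -1.29 with palmitic acid. It was at least 1.5-fold lower with oleic acid too, where the marker list had a median of -0.01. Pdgfrb therefore gives no separate sign of a loss of these cells. An effect of palmitic acid stays open as a hypothesis, together with differences between pools and array-wide effects that move lists together, which 1 array per group leaves untested.

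Most cytokine genes at the top of the scale hardly differed between arrays. Il6, at log2 13.05 in the control, was an exception at -0.59 with palmitic and -0.42 with oleic acid, and Icam1 lay at -0.27 with palmitic acid. A ceiling of the measurement may account for this, since the robust SD of palmitic acid differences was 0.0824 in the 153 genes with a mean at or above 13 and 0.217 in the 3772 genes from 9 to 11, and 0.061 and 0.111 for linoleic acid. Of the cytokine list, the 12 members at or above 13 in the control had a median absolute difference of 0.07 with palmitic acid, and the 10 below 12 one of 0.24. The brightest class also holds ribosomal protein and reference genes, so that a real lack of response in these cytokine genes stays open.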

How the results depend on the processing

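All alternatives reported here were planned. Besides counts and overlaps, list medians were recomputed, and genes named by rank or in advance in the comparisons they were named for. Genes named only as list members were not. Of the correlations, only the Pearson values of differences that share no array were recomputed, with the stricter filter and with no filter. Among the recomputed values, no list median that stood apart, no named difference of at least 1.5-fold and no correlation changed sign. Smaller differences did in places, such as Ccl2 with palmitic acid, from -0.0037 to 0.0052 with centring. Which side held more genes depended on the processing in 3 comparisons. Higher genes were 44.0% for palmitic against linoleic acid and 53.1% with centring, and 52.3% for palmitic against oleic acid and 42.5% with a repeated quantile normalisation. For linoleic acid against the control they were 50%, with 22.2% after centring, 18.2% after a repeated quantile normalisation, 69.0% without the filter and 75% with the stricter filter. Of the counts, 76 of the recomputed values stayed within 1.5 times and 8 moved. Genes higher with linoleic acid than in the control (4) came to 2 with centring, 2 with a repeated quantile normalisation and 20 without the filter, and lower genes (4) to 7, 9 and 9, and to 1 with the stricter filter. Genes lower with linoleic than oleic acid (38) came to 25 with the stricter filter. At 2-fold in place of 1.5-fold, palmitic and oleic acid shared 3 higher genes (14) and 3 lower genes (22), and palmitic and linoleic acid 0 higher genes (1). Apart from the filters and the size, which count fewer or more genes by construction, the cause was not tested. List medians moved by over 0.1 in 8 values and by less in 1204, and differences of named genes by over 0.2 in 16 and by less in 1112, the 16 among dim genes such as Adam4, Rny1, Thap2 and Spata48. Part of the unmoved values could not move. Random lists without matching leave all 174 list medians as they were. Centring shifts a comparison by a small constant, since the array medians lay between 7.07 and 7.13. The overlaps were the same in 13 values and the correlations in 6. The stricter filter and the 2-fold size can only take genes away, so that overlaps of 0 had to stay at 0. The 3 overlaps above 0 all moved at 2-fold. The cholesterol synthesis, fatty acid synthesis, PPAR and stress response lists stood apart in every alternative run for the comparisons where they did so at first; the PPAR list without members of other lists was too small to run. In genes with a mean below the floor the robust SD of differences from the control was 0.137 with linoleic acid and 0.150 with palmitic acid, beside 0.111 and 0.217 from 9 to 11.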

Other observations

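The test of the receptor genes was chosen only after the result was seen.

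With palmitic acid, the list of heat shock genes set as cytosolic stood apart, with a median of 0.21 over 15 genes, 0 of them beyond 1.5-fold. It also holds Hspd1 (0.21) and Hspe1 (-0.05), which code for mitochondrial chaperones. Hspa4l (0.54), Dnajb4 (0.52), Hsph1 (0.43) and Bag3 (0.40) were the highest. Of the 15 genes 12 lay above 0, while Hspa1a lay at 0.01 and Dnajb1 at -0.05. Oxidative phosphorylation genes had a median of -0.12 over 29 genes, with Ndufv2 at -0.29. Among phospholipid and sphingolipid genes, whose median of 0.04 did not stand apart, Pcyt1a, which codes for the rate-limiting enzyme of phosphatidylcholine synthesis, was higher by 1.05 and the glucosylceramide synthase gene Ugcg by 0.92, while Lpcat1 lay at -0.86. Immediate early genes moved both ways, with Jun at 1.53, Dusp1 at 0.95, Ier2 at -0.95 and Dusp2 at -0.71. The zinc exporter gene Slc30a1 was higher by 0.90, in a metallothionein and zinc response list whose median of 0.13 over 6 genes did not stand apart. The metallothionein genes Mt2 (-0.54) and Mt1 (-0.37) lay within 1.5-fold of the control.

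With oleic acid, immediate early genes had a median of 0.11 at percentile 99.89, with Dusp1 at 0.87, Fos at 0.58 and Egr1 at 0.54. With linoleic acid, ribosomal protein genes had a median of -0.08 and oxidative phosphorylation genes of -0.03, both apart from random lists. Few markers of other cell types were kept. With palmitic acid the 3 kept B cell markers had a median of -0.44, the 4 neutrophil markers of -0.21 and the 3 mast cell markers of -0.45, with no percentile for lists this small. Over all measured markers the medians were 0.02 (10 B cell), -0.11 (13 neutrophil) and -0.03 (10 mast cell).

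Differences that share no array were correlated across genes. Oleic acid minus control and linoleic minus palmitic acid gave r = -0.194 (rho = -0.041), linoleic acid minus control and oleic minus palmitic acid r = -0.184 (rho = -0.206), and palmitic acid minus control and linoleic minus oleic acid r = -0.034 (rho = 0.130).

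Gpr85 and Gpr18, receptors of the G protein-coupled family, were among the lowest genes with palmitic acid. A hypothesis is that receptor genes of this family may be lower as a group. Of 70 kept receptor genes, 9 were at least 1.5-fold lower and 3 higher, and of the 66 not named elsewhere 6 and 3. These 66 had a median of -0.08 at percentile 0.81, short of the 0.5 used for lists. The result does not decide it, since leaving out the named receptors lowers the chance of seeing a group effect and including them would count genes that prompted the question.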
